A study of Mus musculus with 4 samples.

How the data were processed

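The series holds expression arrays of mouse GS cells, mGS cells, R1 ES cells and Trp53 knockout GS cells, 4 arrays with 1 per group. Per the labels' protocols, total RNA was extracted with Trizol and biotin-labelled cRNA was made by the standard Affymetrix procedure. The authors deposited 1 intensity per probe set and array on a linear scale; the software that summarised the probes is not given in the sources used here. The deposited intensities have a mean of 500 on every array after 2% of values are trimmed from each end, so the arrays had been scaled to a common mean.

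Of 45101 probe sets, 64 controls were set aside and 45037 used. The log2 medians of the arrays ranged over 0.29 and the 75th percentiles over 0.27. A rule fixed in advance called for quantile normalization when both exceeded 0.2, so log2 values were quantile normalized over the 4 arrays. Such normalization gives every array the same distribution, which hides any change in the total amount of RNA. Probe sets were named from the platform's annotation, which listed 35890, of which 34958 had 1 gene symbol and 932 several. That listing was not limited to the probe sets used. Of the 45037 used, 9160 were not listed and so unnamed here. By gene identifier, 34754 of the named probe sets matched the gene table of assembly GRCm38.p6, which was used for names and chromosomes only. Probe sets with several symbols were left out. A gene took the value of its probe set with the highest mean over the arrays, giving 18193 genes, and disagreement between probe sets was recorded. Trp53 was not analysed here.

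The floor was the array median, 6.37 on the log2 scale or a signal of 82.7. A value under it was raised to it, so that the difference became a bound, and a gene under it on both arrays gave no difference. Genes were counted by a difference of 2-fold. The named genes followed a rule fixed in advance: per comparison the 8 highest and 8 lowest genes above the floor on both arrays, the 6 largest bounds in each direction, members of gene lists with large differences, and 6 genes per direction for the division by medium. Predicted genes were counted and not named.

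A set of 29 gene lists with 501 members, 464 of them measured, was fixed in advance. They cover spermatogonial stem cell, pan-germ cell, spermatogonial differentiation, meiosis, pluripotency, cells resembling the early cleavage embryo, LIF-STAT3 response, primed epiblast, endoderm, mesoderm, neuroectoderm, trophectoderm, p53 target, proliferation, cyclin and CDK inhibitor, paternally and maternally expressed imprinted, DNA methylation and Polycomb, FGF-ERK feedback, glycolysis and hypoxia, cholesterol synthesis, interferon response, heat shock and unfolded protein, fibroblast feeder, Sertoli, Leydig, leukocyte, housekeeping and sex chromosome genes. Each list's median log2 difference was set against 10000 random lists of the same size, matched on mean expression in 20 bins. The 95% interval of a median comes from the ranked members and covers the spread between members, not between cultures. Percentiles describe these arrays and are not tests.

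The steps were tested on simulated data for mGS against GS over 11923 genes. Of planted 2-fold and 4-fold differences, 49% and 93% were recovered at 2-fold or more. When the whole scatter between the knockout and GS arrays was taken as noise, an upper bound, 18.5% of unchanged genes came out at least 2-fold apart. Of random unchanged lists, 4.5% fell outside the central 95%. Random picks were set against random picks there, so such a share follows from the design. It cannot show how often lists of genes that vary together fall outside. On the real arrays, 55 list medians did so over the comparisons of mGS, ES and knockout with GS and of ES with mGS. A position outside the random lists was therefore common and does not single out a list.

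Alternatives were the values as deposited, centring on array medians, the mean of a gene's probe sets, leaving out probe sets prone to cross-hybridisation, floors at the 30th and 60th percentiles, no floor, a pseudocount of 32 and keeping probe sets with several symbols. Against the quantile values, centring on medians shifted the median of all genes by -0.16 for knockout against GS and by -0.11 for ES against mGS. Differences are relative to the main normalization. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.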

Results

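RNA of 4 mouse cell cultures was hybridised to Affymetrix oligonucleotide arrays, with 1 array for each group. Germline stem (GS) cells are spermatogonial stem cells grown from the testis, and multipotent germline stem (mGS) cells are cells with properties of embryonic stem cells that arise in such cultures. The third culture was the embryonic stem (ES) cell line R1, and the fourth was GS cells of Trp53 knockout mice, whose title also names the strain ICR. The GS and knockout GS cells were grown in a GS medium based on StemPro, and the mGS and ES cells in a standard ES cell medium. Each group has 1 array, so no difference has a replicate check and no p-value is given; differences are described by their size. On the arrays as deposited, the median signal was 80.1 for GS, 75.7 for mGS, 83.5 for ES and 92.3 for the knockout. Signals under a floor of 82.7 were set to that floor, and a difference against it is given as at least N-fold. The number of arrays limits the precision of every value.

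Added poly-A control RNAs, which enter a sample before labelling, split the arrays into pairs. The dap control, as the median of 6 probe sets, read 271 on the GS array and 255 on the mGS array, against 2545 on the ES array and 3054 on the knockout array. The comparisons of mGS with GS and of ES with knockout lie within these pairs, and those of ES with mGS and of knockout with GS cross them.

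The arrays paired by culture medium. Across 12897 genes above the floor on at least 1 array, the GS and knockout arrays had a Pearson correlation of 0.908 and the mGS and ES arrays one of 0.898, while the other 4 pairs lay between 0.700 for ES with knockout and 0.767 for GS with mGS. Genes are not independent replicates, so these correlations describe the arrays only. At least 2-fold in all cross pairs, 986 genes were higher and 1081 lower on the mGS and ES arrays than on the GS and knockout arrays, 2067 in all. The other ways of dividing the arrays into pairs gave 65 genes for ES and knockout against GS and mGS, and 43 for mGS and knockout against GS and ES. The genes with the widest gap toward the ES medium were the Nodal co-receptor Tdgf1, at least 154-fold, the RNA-binding protein gene L1td1, at least 153-fold, and the 5-methylcytosine dioxygenase gene Tet1, at least 62.9-fold. Stmn2, Mtm1 and Nanog followed, 61.7-fold, 59.1-fold and at least 48.1-fold. Toward the GS medium they were the germ cell mRNA export gene Nxf2, at least 103-fold, the transketolase-like gene Tktl1, at least 77.5-fold, and Taf9b, at least 70.7-fold. Tex101, Taf7l and Zbtb16 followed, 68.7-fold, 65.9-fold and 64.8-fold. Cell type and medium changed together in this division, and without the floor it held 3215 genes.

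**Figure D1:**
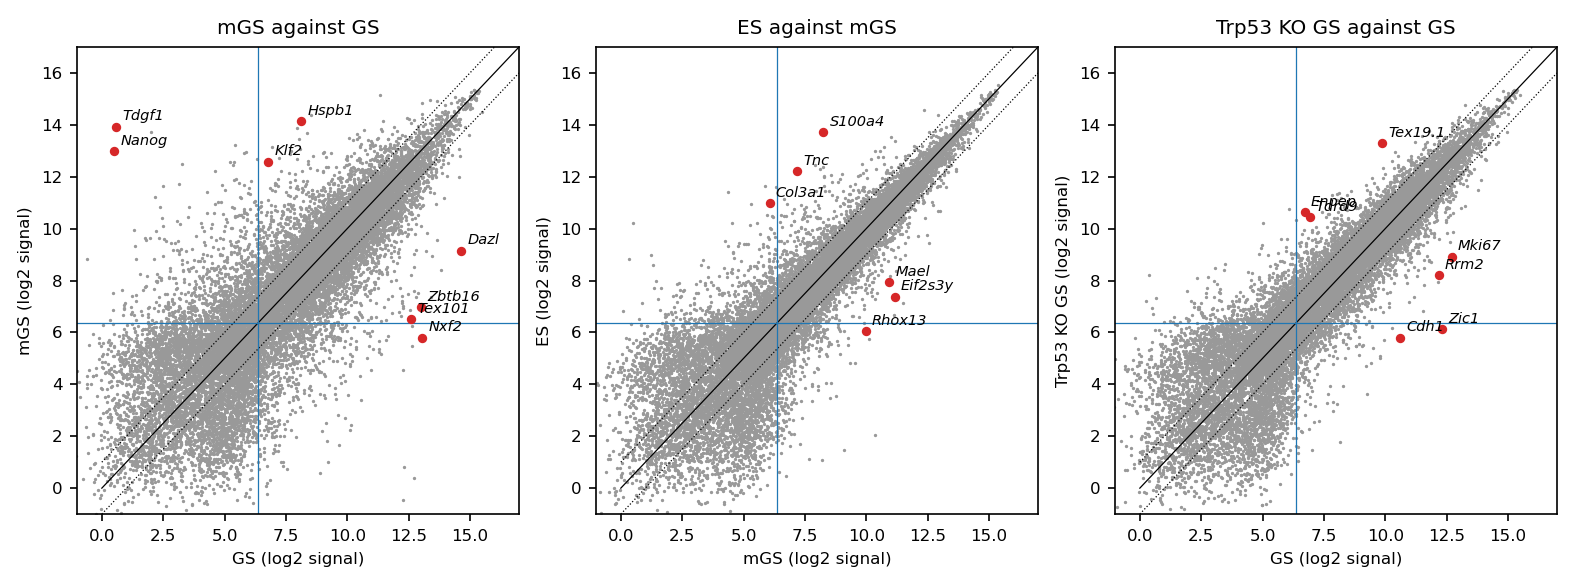
Normalised log2 signal of each gene on the array named on the vertical axis against the array named on the horizontal axis, with 1 grey point per gene. The solid line marks equal signal, dotted lines a 2-fold difference and blue lines the floor, and red points are named genes. Nanog and Tdgf1 lie under the floor on the GS array and far above it on the mGS array.

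The series names the comparison of mGS with GS cells as a search for molecules that might take part in the conversion of GS into mGS cells. Medium and cell type changed together between these arrays, so no difference can be assigned to either. Nor do arrays of established cultures show which molecules take part in a conversion. Pluripotency transcripts were higher on the mGS array and most germ cell transcripts were lower. Tdgf1 was at least 189-fold higher, L1td1 at least 165-fold, Dnmt3l, a cofactor of the de novo DNA methyltransferases, at least 117-fold, and Nanog, a core pluripotency factor, at least 97.3-fold. Zbtb16, a transcription factor of undifferentiated spermatogonia, was 64.8-fold lower, and the germ cell RNA-binding protein gene Dazl 45.2-fold lower. In all, 1838 genes were at least 2-fold higher and 1976 at least 2-fold lower on the mGS array among 11981 compared, of which 610 and 489 differed at least 4-fold. The median absolute log2 difference was 0.64. The differences had a standard deviation of 1.24, and those from separate probe sets of a gene one of 0.50 over 4474 genes. Without the floor the counts were 3999 higher and 4021 lower.

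Of 33 pluripotency genes compared, 31 were at least 2-fold higher on the mGS array, with a median log2 difference of 3.83 (95% interval over members 2.55 to 4.96), above all 10000 random lists. Eras and Gdf3 were at least 73.6-fold and 47.0-fold higher, and Klf2 and Utf1 56.05-fold and 37.1-fold. The GS array already carried Pou5f1, which was 5.86-fold higher on the mGS array, and Sox2, which was 10.8-fold higher. The other members were Lin28a, with a log2 difference of 0.22, and Tcl1, with one of -1.84. Of 23 pan-germ cell genes, 20 were at least 2-fold lower, with a median of -3.10. They included the surface glycoprotein gene Tex101, 68.7-fold, Taf7l, 65.9-fold, and the RNA helicase genes Mov10l1 and Ddx4, 40.3-fold and 16.5-fold. Tex19.1 went the other way and was 5.69-fold higher. Of 16 spermatogonial stem cell genes, 11 were at least 2-fold lower, with a median of -2.07. Of the genes for the receptor of the growth factor GDNF, Ret was at least 25.1-fold lower and Gfra1 16.1-fold lower. Upp1 and Etv5 were 39.9-fold and 3.25-fold higher. Of 18 meiosis genes, 16 were at least 2-fold lower and none 2-fold higher, with a median of -1.33; the synaptonemal complex genes Sycp1 and Sycp2 were 41.7-fold and 13.2-fold lower. Of 9 genes of spermatogonial differentiation, 6 were lower, Ccnd2 by 23.2-fold, and 2 higher, Kit by at least 8.47-fold, with a median of -2.23.

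Transcripts of glycolysis were higher and those of cholesterol synthesis lower on the mGS array. Of 15 glycolysis and hypoxia genes, 8 were at least 2-fold higher and none 2-fold lower, with a median of 1.48, above all random lists. The phosphofructokinase genes Pfkp and Pfkl were 39.4-fold and 23.7-fold higher, Pgk1 9.52-fold and the lactate dehydrogenase gene Ldha 6.51-fold. Of 15 cholesterol synthesis genes, 10 were at least 2-fold lower, with a median of -1.19; Cyp51 was 4.80-fold and Hmgcs1 3.48-fold lower. Chromatin genes went both ways: among 20 DNA methylation and Polycomb genes, 10 were higher and 4 lower, with a median of 0.74. Tet1 was at least 67.5-fold and Tet2 20.9-fold higher, while the Polycomb gene Bmi1 was 34.0-fold lower. Of 33 p53 target genes, 12 were at least 2-fold higher and 3 lower, with a median of 0.45, at the 99.4th percentile of random lists. Ak1 was 20.8-fold, the apoptosis effector gene Perp at least 16.4-fold and Psrc1 14.4-fold higher. The proliferation list had a median of -0.30 over 22 genes, of which 1, Birc5, was 2.19-fold higher. No housekeeping gene among 12 differed by 2-fold. The knockout array, in the GS medium, also had a glycolysis and hypoxia median above GS, 0.52, with 4 of 15 genes at least 2-fold higher and 2 lower. Its cholesterol synthesis median against GS was -0.47, with 4 of 15 genes lower and 1 higher. Smaller differences in these directions were thus not particular to the mGS array.

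The other genes with the largest differences included Ooep, an oocyte gene, 73.8-fold higher, the small heat shock protein gene Hspb1, with a log2 difference of 6.02, the actin-binding Tmsb4x, 60.4-fold, and Mtm1, 59.1-fold. Basp1 and Akap12 were 46.3-fold and 42.8-fold higher, and the homeobox gene Rhox5 and the gap junction gene Gja1 at least 95.2-fold and 93.3-fold. Camk2n1, the germline Polycomb gene Scml2 and the testis ADP/ATP carrier gene Slc25a31 were 51.2-fold, 43.6-fold and 42.9-fold lower. Nxf2 was at least 103-fold, Bnc1 at least 81.2-fold, Tktl1 at least 77.5-fold, Taf9b at least 76.5-fold, the zinc finger gene Zic1 at least 61.5-fold and Tex13b at least 60.2-fold lower. Fibroblast genes were higher on the mGS array as well, 13 of 18 by at least 2-fold with a median of 1.98, among them Ccn2 by 21.3-fold and Tagln by at least 14.1-fold. With the knockout array in place of the GS array, a comparison added after seeing the data, 2112 genes were at least 2-fold higher and 2652 lower on the mGS array.

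**Figure D2:**
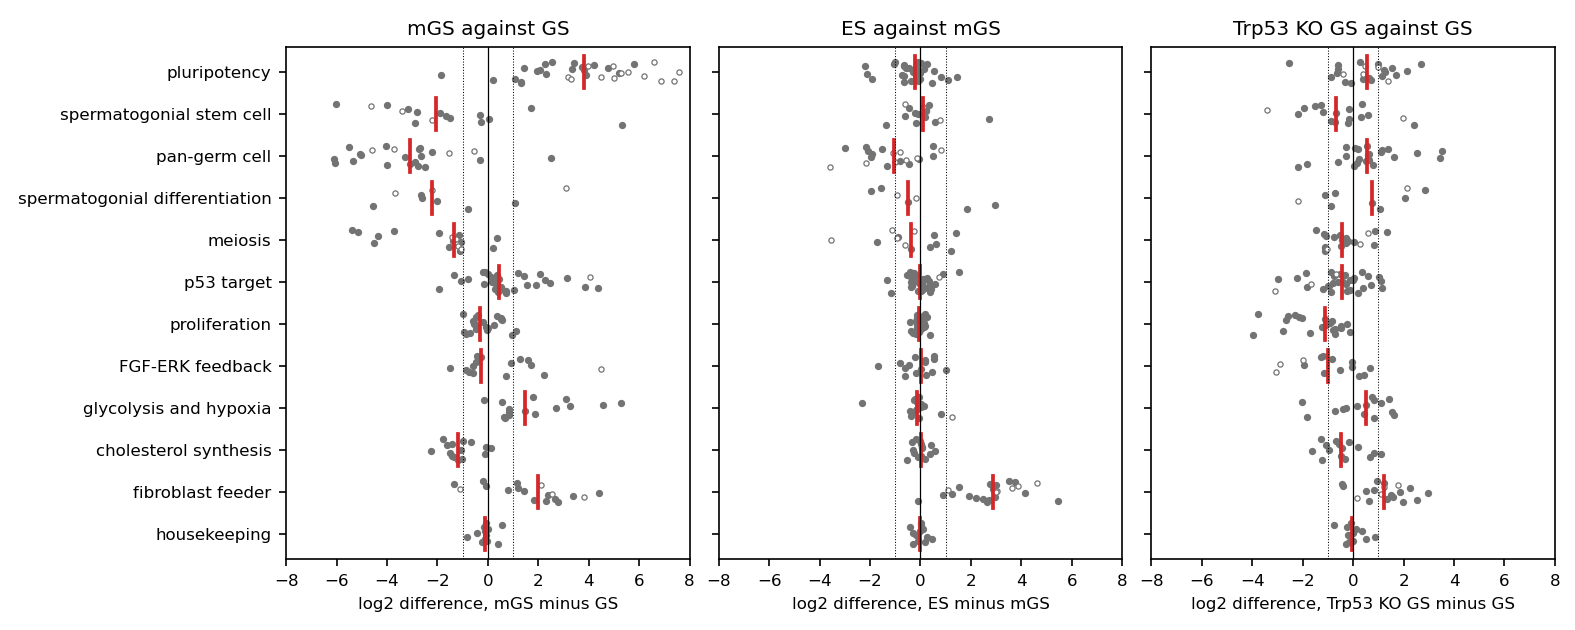
Log2 differences of the members of 12 gene lists in 3 comparisons, with 1 point per gene compared, open points for differences against the floor and red bars for list medians. Dotted lines mark a 2-fold difference. For mGS against GS the pluripotency median stood at 3.83 and the pan-germ cell median at -3.10, while the housekeeping medians lay near 0 in all panels.

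The comparison of ES with mGS cells shows how far the mGS array stood from that of an ES line in the same kind of medium. Most pluripotency genes lay within 2-fold between the arrays, and fibroblast genes were higher on the ES array. S100a4 was 44.1-fold, the matrix glycoprotein gene Tnc 32.7-fold and the proteoglycan gene Bgn 23.4-fold higher, and the fibrillar collagen gene Col3a1 at least 24.4-fold higher. Germ cell genes such as Mael, of the piRNA pathway, 7.96-fold, and the meiotic gene Hormad1, at least 11.7-fold, were lower on the ES array. In all, 815 genes were at least 2-fold higher and 606 lower among 11816, of which 191 and 75 differed at least 4-fold. The median absolute log2 difference was 0.35. The differences had a standard deviation of 0.72, against 0.45 between probe sets of a gene above the floor on both arrays. With arrays centred on their medians the counts were 722 higher and 758 lower, with the values as deposited 850 and 496, and without the floor 2747 and 2574.

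Of 23 fibroblast genes compared, 21 were at least 2-fold higher on the ES array and none lower, with a median of 2.88 (95% interval over members 2.19 to 3.52), above all random lists. Fbln2, Col1a2 and Col1a1 were 17.5-fold, 13.6-fold and 11.5-fold higher. Genes with the largest differences outside the list included the cadherin gene Cdh11, at least 39.0-fold, Tm4sf1, at least 37.2-fold, the chemokine gene Ccl2, at least 32.8-fold, and the metalloproteinase gene Mmp3, at least 17.9-fold. Igf2bp3 was 22.5-fold, Emp1 18.2-fold, Slc27a2 17.9-fold and Loxl3 15.99-fold higher, and Olig1 at least 24.1-fold.

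Of 33 pluripotency genes, 26 lay within 2-fold, with a median of -0.23, at the 1.86th percentile of random lists. Lefty1 was 2.70-fold higher on the ES array, and so was Lin28a, 2.13-fold, although another of its probe sets went the other way by 2-fold or more. Tbx3, Nr5a2 and Prdm14 were 4.62-fold, 4.37-fold and 3.76-fold lower, Klf2 2.05-fold and Nanog 2.02-fold. Of 20 pan-germ cell genes, 10 were at least 2-fold lower on the ES array and none higher, with a median of -1.05; Rhox13 was at least 12.1-fold and Dazl 4.44-fold lower. Of 18 cyclin and CDK inhibitor genes, 6 were higher and none lower by 2-fold, with a median of 0.46, among them Ccnd2, 7.84-fold, and Cdkn2b, 5.67-fold. The spermatogonial stem cell, glycolysis, cholesterol synthesis, proliferation, p53 target and housekeeping medians were 0.10, -0.13, 0.01, -0.08, -0.01 and 0.00. Lama3, the histone gene H3f3b and the Y-linked gene Eif2s3y were 22.1-fold, 20.2-fold and 13.7-fold lower on the ES array. The H3f3b value rests on 1 probe set, which read 2855 on the mGS array and 141 on the ES array, not far above the floor. No other probe set was available to check it, so it may not stand for the gene's total RNA. Pnma5, Rpl39l, Ccnb1ip1 and Arhgap30 were 8.73-fold, 8.43-fold, 8.40-fold and 8.08-fold lower, and Apoc2, the Y-linked Uba1y and A2m at least 13.5-fold, 9.05-fold and 7.76-fold. The poly-A controls differed between these arrays, as given above. Genes of chromosomes 1 and 11 were higher as groups on the mGS array than on the ES array, each by 0.38 on the log2 scale, and without chromosomes 1, 6, 11, 16, X and Y the lower genes numbered 356, a setting chosen after seeing the data that also leaves fewer genes.

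In the comparison of Trp53 knockout GS cells with GS cells, the signal of Trp53 itself was not analysed here, so the label was not checked at the targeted gene. Most pan-germ cell genes lay within 2-fold of GS or were higher on the knockout array, while the spermatogonial stem cell and meiosis medians were -0.67 and -0.46. The genes at least 2-fold lower included 13 of 22 proliferation genes and 7 of 14 genes of the FGF-ERK feedback list. Which signal lowered the feedback genes was not tested. Rrm2, a subunit of ribonucleotide reductase, was 15.6-fold lower, the proliferation marker Mki67 13.8-fold and the PCNA-binding Pclaf 13.3-fold. The transcription factor gene Zic1 was at least 61.5-fold and the E-cadherin gene Cdh1 at least 18.6-fold lower. The piRNA pathway gene Tdrd9 and Tex19.1, a gene of retrotransposon control, were 11.6-fold and 10.8-fold higher. In all, 1135 genes were at least 2-fold higher and 805 lower on the knockout array among 11623, of which 128 and 122 differed at least 4-fold. With arrays centred on their medians the same comparison gave 838 higher and 1072 lower, and without the floor 3166 and 2597.

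All 22 proliferation genes were lower on the knockout array, 13 of them by at least 2-fold, with a median log2 difference of -1.10 (95% interval over members -2.30 to -0.71), below all random lists. Birc5, Plk1 and Top2a were 6.87-fold, 6.27-fold and 4.94-fold lower. Hybridisation controls were lower on this array too, bioC by 5.43-fold against the mean of the others, and loss of signal at particular probe sets was not tested. Of 32 p53 target genes, 7 were at least 2-fold lower and 3 higher, with a median of -0.46 (95% interval -0.89 to -0.0018), also below all random lists. Epha2 was at least 8.49-fold lower, Plk2 4.66-fold and Ccng1 3.69-fold, while Ddit4, Xpc and Tnfrsf10b were 2.18-fold, 2.18-fold and 2.05-fold higher. The classical targets Cdkn1a and Mdm2 had log2 differences of -0.88 and 0.34. Of 14 genes of FGF-ERK feedback, 7 were at least 2-fold lower and none higher, with a median of -1.001; the ERK phosphatase gene Dusp4 and Etv4 were at least 8.24-fold and 7.48-fold lower. Of 11 genes of the LIF-STAT3 response, 5 were lower, led by Socs3, 4.34-fold, with a median of -0.28, at the 8.10th percentile. The cyclin gene Ccnd1 was 7.95-fold lower and the inhibitor gene Cdkn1b 4.84-fold higher, among 18 cyclin and CDK inhibitor genes with a median of -0.28.

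Germ cell lists differed in direction. Of 23 pan-germ cell genes, 7 were at least 2-fold higher on the knockout array and 2, Rhox13 and Usp26, were lower, with a median of 0.55. Piwil4 was 5.76-fold higher. Of 17 spermatogonial stem cell genes, 6 were lower, Lhx1 by at least 10.7-fold and Itga6 by 4.53-fold, and 2 higher, with a median of -0.67. Of 9 genes of spermatogonial differentiation, 4 were higher and 2 lower, with a median of 0.74; the retinoic acid responsive Stra8 was 7.19-fold, Neurog3 4.14-fold and Kit at least 4.36-fold higher. Of 20 meiosis genes, 7 were lower and 1, Sycp3, higher, with a median of -0.46. Of 24 pluripotency genes compared, 8 were at least 2-fold higher, with a median of 0.54 (95% interval over members -0.31 to 1.23), at the 99.99th percentile of random lists. The interval includes 0, and the median was 0.27 with the mean of a gene's probe sets and 0.33 without chromosomes 1, 6, 11, 16, X and Y. The percentile may be too high, because random lists were matched on the mean over all arrays. The median signal of the list was 204 on the GS and 345 on the knockout array, against 5116 on mGS and 3979 on ES. Klf2 was 6.45-fold, Dppa3 4.40-fold and Utf1 3.27-fold higher, and Sox2 was 5.79-fold lower. Nanog and Tdgf1 were under the floor on both arrays. Of 19 fibroblast genes, 12 were at least 2-fold higher and none lower on the knockout array, with a median of 1.23, and 5 of 16 genes of heat shock and the unfolded protein response were higher, among them Asns, 3.79-fold, with a median of 0.71.

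The largest other differences on the knockout array were Enpep, an aminopeptidase gene, 15.2-fold higher, Lmo1, 11.04-fold, Golt1b, 9.77-fold, Serpini1, 9.66-fold, the transcription factor gene Cebpa, 9.55-fold, and Phlda2, 9.24-fold. Tubb2b, Lgals2, Dpep1, Pde6b, Cerk and Coch were at least 21.2-fold, 15.6-fold, 14.5-fold, 9.50-fold, 9.29-fold and 7.98-fold higher. The adhesion gene Mpzl2 was 26.1-fold lower, the neurofilament gene Nefm 18.4-fold, Id3 14.2-fold, Plekhh3 13.8-fold and Dusp9 13.2-fold. Nav1, Skor1 and Crmp1 were at least 14.8-fold, 11.95-fold and 10.7-fold lower. Genotype, strain and culture are not separable here, the poly-A controls differed between the arrays, and genes of chromosome 6 were higher as a group on the knockout array by a log2 shift of 0.45.

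**Figure D3:**
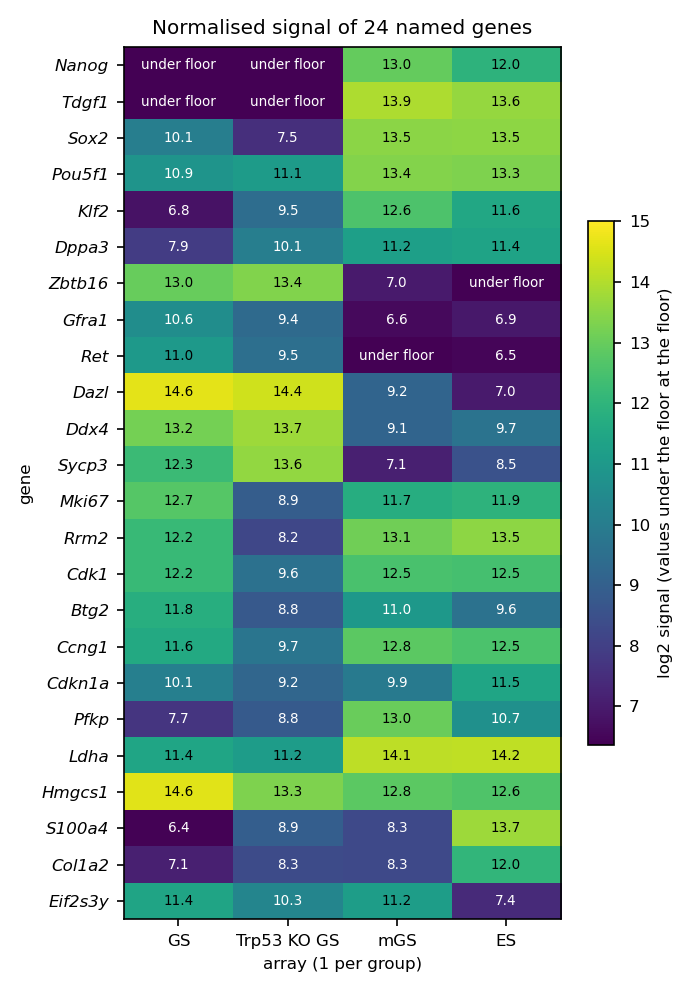
Normalised log2 signal of 24 named genes on the 4 arrays, printed in each field and shaded from the floor upward. The GS and knockout columns share Zbtb16, Dazl and Ddx4, the mGS and ES columns share Nanog and Tdgf1, and Mki67 and Rrm2 are lowest in the knockout column.

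Whether the knockout array leaned toward the mGS array was asked by comparing their differences from GS. Across genes these correlated at 0.11 with a covariance of 0.10, whereas 100 simulations of unchanged arrays against a shared array gave 0.50 and 0.25. The simulations took the whole scatter between knockout and GS as noise, which is an upper bound on the noise. Equal noise on every simulated array sets the correlation near 0.50 whatever the size of the noise. Higher in both by 2-fold were 262 genes and lower in both 240, against 162 and 123 for independent lists, and 278 went opposite ways. The simulated unchanged arrays gave 693 genes in the same direction, more than the 502 observed. The noise was set high and the mGS array was treated as unchanged. Falling under the simulated values therefore does not decide whether the knockout array leaned toward the mGS array. Over all genes the knockout array was not nearer to it than the GS array was. The mGS array had a Pearson correlation of 0.726 with the knockout array and 0.767 with the GS array. It differed by 2-fold from the knockout array at 2112 higher and 2652 lower genes, and from the GS array at 1838 and 1976. With 1 array each, these values describe the arrays only. The pair that shares no array, knockout minus GS and ES minus mGS, correlated at 0.064. That pair cannot decide the question, because ES minus mGS holds no change from GS toward mGS and both differences cross the poly-A pairs. The differences of mGS from GS and of ES from knockout, which also share no array, correlated at 0.72, with 1178 genes higher in both and 1286 lower in both, against 330 and 406 for independent lists.

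The comparison of ES with GS cells completes the set and shares the GS array with the first comparison. Medium and cell type changed together here too. On the ES array 2106 genes were at least 2-fold higher and 2083 lower among 12107. The values as deposited gave 1905 and 2190, centring on medians 1912 and 2419, and no floor 4168 and 4100. S100a4 was 158-fold, Tmsb4x 76.9-fold and Grb10, an imprinted adaptor gene, 44.5-fold higher, and Gja1 at least 142-fold. Dazl was 201-fold lower, Mael 51.4-fold, Slc25a31 at least 175-fold and Uba1y at least 157-fold. Of 33 pluripotency genes, 29 were at least 2-fold higher, with a median of 3.56, and of 23 pan-germ cell genes 20 were lower, with a median of -4.30. Of 23 fibroblast genes, 22 were higher, with a median of 4.50. The spermatogonial stem cell, glycolysis and cholesterol synthesis medians were -2.22, 1.41 and -1.35. The differences from the shared GS array correlated at 0.85 with those of mGS, with 1335 genes higher in both and 1483 lower in both, against 300 and 319 for independent lists. The simulated unchanged arrays gave a correlation of 0.50, which equal noise sets, and 693 genes in the same direction.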

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

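The tests on fibroblast genes and on proliferation genes in this part were all chosen after the results were seen. The signals of added control RNAs lie outside the gene comparisons and drew attention because they divide the arrays in a way the groups do not. On the ES and knockout arrays the poly-A control dap was 10.6-fold higher than on the GS and mGS arrays, by the median of 6 probe sets. For lys, phe and thr these medians lay under the floor on the GS and mGS arrays, although a few single probe sets lay above it, and were at least 2.98-fold, 3.80-fold and 7.68-fold higher. These RNAs are added before labelling, and the labels do not say how much was added. Hybridisation controls were lower on the knockout array than the mean of the other arrays, bioC by 5.43-fold, bioB by 1.71-fold, bioD by 1.63-fold and cre by 1.28-fold. The median of 3 probe sets for 18S ribosomal RNA was 2.34-fold lower on the knockout array, and the set for its 5' part alone read 1414 against 20754 to 32246 on the others.

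Fibroblast genes were higher on the ES array than on the mGS array. RNA of feeder fibroblasts stays open, because the share of compared members at least 2-fold higher, 91.3%, is the pattern itself and fibroblast-like cells would give it too. S100a4, Col1a2 and Col1a1 had signals of 13496, 4195 and 2805 on the ES array against 306, 310 and 245 on the mGS array; on the GS array 15 of the 24 measured members were already above the floor, and none belongs to another list. A labelling batch shared by the ES and knockout arrays was argued against as the whole cause, because the 19 members compared in both pairs had a median of 2.70 for ES against mGS and 1.23 for knockout against GS, a gap of 1.46. Fibroblast-like cells arising from the ES cells stay open as well, because 16.7% of mesoderm genes compared were at least 2-fold higher and mature fibroblasts need not carry early mesoderm transcripts, and the labels do not state whether feeders were used.

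Proliferation genes were lower on the knockout array than on the GS array, 13 of them by at least 2-fold. Dilution by fibroblast RNA would lower all germ cell transcripts alike, and as the whole cause it was argued against by the pan-germ cell median, which was 0.55 higher on the knockout array (95% interval over members 0.084 to 1.11). The spermatogonial stem cell and meiosis medians, -0.67 and -0.46, and the fibroblast median, 1.23, lay in the direction that dilution gives, so a part played by it stays open. Compression of bright signals was argued against with the values as deposited, where these genes had a median gap of -0.97 to other genes of the same brightness; loss of signal at particular probe sets, as seen for bioC, was not tested. Fewer dividing cells remain a candidate explanation, but genotype, strain and the state of the culture cannot be told apart with 1 array per group.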

How the results depend on the processing

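The settings without chromosomes 1, 6, 11, 16, X and Y, with the knockout array in place of GS, and without the ES or the knockout array in the division by medium were chosen after seeing the data; all others were chosen before the data were examined. No paired analysis was possible because each group has 1 array. Under every setting run, the list medians that answer a comparison kept their direction: pluripotency for mGS against GS spanned 3.28 to 4.21, proliferation for knockout against GS -1.34 to -1.05, and p53 targets -0.65 to -0.35. The dim-signal floor moved counts most, and admitting dim genes adds genes by construction. With the floor at the 30th percentile, ES against mGS gave 1397 higher and 1167 lower genes, knockout against GS 1759 higher, the correlation of knockout and mGS differences from GS was 0.17, and the mean correlation within a medium exceeded that between media by 0.10. That excess was 0.22 with the floor at the 60th percentile. With no floor, the division by medium gave 3215 genes, mGS against GS 3999 higher and 4021 lower, ES against mGS 2747 and 2574, knockout against GS 3166 and 2597, ES against GS 4168 and 4100, the correlation was 0.33 and the excess 0.075. With the pseudocount of 32, ES against mGS had 974 lower genes, the correlation was 0.17 and the excess 0.086. Without the named chromosomes ES against mGS had 356 lower genes. The Sertoli median for knockout against GS, -0.71 over 4 genes, reversed to 0.25 with no floor and 0.14 with the pseudocount; the cause was not tested. Other list medians moved in 33 cases and stayed in 1018. Staying meant within the interval over members or, for lists too small to have one, within the standard deviation between probe sets. Named genes moved in 178 cases and stayed in 895, with none reversed. Signals near the floor limit every bound.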

Other observations

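The tests of the chromosome shifts, by gene order, by the share of genes above the other chromosomes and by brightness, were all chosen after the result was seen. Imprinted genes differed in both directions between the cultures. On the mGS array against GS, Meg3 was 18.8-fold, Phlda2 10.7-fold and Peg3 8.35-fold higher, while Cdkn1c was 9.75-fold lower. Igf2 was 13.9-fold lower. Another of its probe sets gave -0.10 on the log2 scale after values were raised to the floor, which may be a bound from a dim probe set. The maternally expressed list had a median of 1.10 over 12 genes and the paternally expressed list 0.69 over 17. On the knockout array against GS, Dlk1 was 6.03-fold and Sgce 4.91-fold higher and Igf2 8.04-fold lower. The other Igf2 probe set again gave -0.10 after flooring, with the same limit. The list medians were -0.20 and 0.24. Between ES and mGS, Meg3 was 5.28-fold lower and Igf2 5.51-fold higher on the ES array, with medians of 0.29 and -0.13.

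Among the remaining lists for mGS against GS, 7 of 12 primed epiblast genes were at least 2-fold higher, Otx2 by at least 13.2-fold, with a median of 1.23. Of 8 trophectoderm genes 4 were higher, Tfap2c by at least 25.7-fold, with a median of 0.81, and of 8 Sertoli genes 5, led by Rhox5, with a median of 1.82. Neuroectoderm had a median of 1.55 over 6 genes, mesoderm 0.73 over 7 and endoderm 0.24 over 9, in which Foxa2 was at least 8.29-fold lower. The heat shock list split: Hspb1 was higher, with a log2 difference of 6.02, and Hspa1b and Hspa1a were 18.5-fold and 14.4-fold lower, with a median of 0.67 over 16. The feedback list of FGF-ERK signalling had a median of -0.27 over 15 with Myc at least 22.2-fold higher, LIF-STAT3 response 0.14 over 12, cyclins and CDK inhibitors -0.17 over 18, interferon response -0.73 over 9, leukocyte genes 0.27 over 4, and genes of cells resembling the early cleavage embryo 0.19 over 3. Of 2 Leydig genes compared, Cyp11a1 was at least 3.99-fold higher.

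Y-linked genes differed between the arrays. Uba1y read 12975 on the GS array, 15124 on the knockout array, 748 on the mGS array and 28.2 on the ES array. Eif2s3y read 2716, 1272, 2292 and 167 in the same order. Usp9y read 1460, 1283, 19.7 and 15.8. Uty read 464, 892, 455 and 73.3, Kdm5d 479, 827, 80.4 and 32.4, and Zfy2 798, 394, 85.3 and 43.7. Orly was dim on all arrays. Eif2s3y and Uty thus stayed near their GS signal on the mGS array. On the ES array all of these genes but Eif2s3y lay under the floor. The sex chromosome list had a median of -1.39 over 6 genes for mGS against GS, where Xist was at least 4.61-fold higher.

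Genes of chromosome 6 on the knockout array, and of chromosomes 1 and 11 on the mGS array, were shifted upward as groups. For mGS against GS the median log2 differences were 0.26 for chromosome 1 and 0.19 for chromosome 11. Chromosomes 9 and 5 had medians of -0.23 and -0.18 in the same comparison. Differences of the size seen for chromosome 11 against GS thus occurred in both directions, which limits their reading as a gain. Gain of a chromosome copy may underlie the chromosome 6 shift of 0.45 against GS over 576 genes, as its lowest value over 3 stretches by gene order was 0.42, and 74.5% of its genes lay above the median of other chromosomes, which argues against a few strong genes. For chromosomes 1 and 11 on the mGS array against GS the lowest stretch was 0.13 and the lowest share 60.9%. That comparison leaves a gain and a few strong genes both open. Against the ES array the lowest stretch was 0.32 and the shares were 74.2% and 78.4%, which argues against a few strong genes for the shift between mGS and ES. A difference between arrays that depends on brightness was argued against for chromosomes 6 and 1, whose lowest shifts against genes of the same brightness were 0.44 and 0.33. For chromosome 11 the lowest such shift was 0.247, against 0.259 before matching. It lay just under the limit of 0.25, so brightness stays open there, although matching changed the shift little. Strain or culture differences stay open as untested, and no DNA was measured. Genes of chromosome 16 on the knockout array had a smaller shift of 0.19 against GS, with a lowest stretch of 0.088.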
